A study of Mus musculus with 6 samples.

How the data were processed

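Messenger RNA levels were measured on 6 Affymetrix arrays of the mouse embryonic stem (ES) cell line A3-1. Per the labels' protocols, the cells grew with serum and LIF, a cytokine that keeps mouse ES cells undifferentiated. They were left untreated, given a small interfering RNA (siRNA) against green fluorescent protein (siGFP, the control siRNA) or given an siRNA against Lin28a (siLin28a), and the labels give 48 h with siRNA for both siRNA groups. Each group has 2 arrays, numbered replicate 1 and 2, and each siRNA group received 1 siRNA sequence. Total RNA was taken with Trizol, and biotin-labelled targets were made from it, per the labels' protocols. Per the submitters' processing notes, the deposited values were made with Affymetrix Expression Console and RMA, which corrects background, quantile normalizes the arrays and summarises the probes of each probe set. Versions of these tools, the array's library files and any genome build are not given in the sources used here. The deposited values were read as log2 expression, the scale on which RMA writes its values, and all of them are in steps of 0.1. The labels do not say whether the 2 arrays of a group came from separate cultures. P-values for rows therefore measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

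The value table holds 35556 probe sets, called rows from here on. A probe annotation made from the array platform's own table named at least 1 gene for 23410 rows, and these were tested. It named 1 gene symbol for 21797 rows, which cover 19946 genes, and several symbols for 1613 rows. The other 12146 rows carry no gene in that annotation and were tested apart. Symbols of 21698 rows with 1 symbol were matched by Entrez number to a table of RefSeq genes, and 0 symbols needed an update. No gene is named from a row with several symbols, except where the closing section describes copies of a gene family that share rows. Genes without a row of their own were not analysed here.

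The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without a trend), two-sided, on all 6 arrays in 3 groups, so that the groups shared 1 estimate of the spread with 3 residual degrees of freedom. The prior added 3.19 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 23410 rows of a comparison, with a threshold of 0.05 and no filter on dim rows. Errors of fold changes are limma's moderated standard errors (SE), and n is 2 arrays per group. An exact two-sided permutation test of 2 arrays against 2 cannot give a p under 0.333, so no permutation p is given for single genes. A gene with several rows was represented in the gene lists by its brightest row.

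The text names the target Lin28a, the genes Pou5f1, Sox2, Nanog and Lin28b in every comparison, and, because no row passed the threshold, the 5 rows with the smallest unadjusted p in each direction. Such rows had 1 symbol, no overlap between the arrays of the 2 groups, and a mean of at least 6 in the higher group; predicted genes, Rik clones and olfactory or vomeronasal receptors were passed over. Also named are the 2 members of each gene list with the largest log2 fold change in size. Members that pass when adjusted over their list alone are named too, which was decided after their values were seen. Where the rule did not name them as well, their values without 1 array were not examined.

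The 26 gene lists were tested with camera (limma) at its preset inter-gene correlation of 0.01, with adjustment over the 78 tests of 26 lists in 3 comparisons. The lists hold let-7 target mRNAs; LIN28, terminal uridylation and small RNA machinery; naive pluripotency; primed epiblast; mesoderm and definitive endoderm; primitive endoderm; neural ectoderm; trophoblast; feeder fibroblasts; the 2-cell-like state; germline genes; the unfolded protein response through ATF6 and XBP1; the integrated stress response through ATF4; ER translocation and N-glycosylation; surface receptors and adhesion proteins of ES cells; the interferon response; p53 targets; the cell cycle; replication-dependent histones; ribosomal proteins; glycolysis; oxidative phosphorylation; cholesterol biosynthesis; the lysosome; immediate early genes; and housekeeping reference genes. Camera compares a list with all other genes, and its call for a list is what the text means by a list that rose or fell. At the preset correlation its p measures a list's shift against the spread over genes, so it can be very small with 2 arrays per group. Camera was also run with an estimated correlation, which with 6 arrays is itself uncertain. Its p then also rests on the 3 residual degrees of freedom. The estimated correlation was 0.55 for the ATF4 list, 0.37 for oxidative phosphorylation, 0.35 for histones and 0.10 for the naive list. It was −0.03 for the primed list and −0.02 for p53 targets, under the preset, so correlation between genes did not raise their p. The fry test was run as well; it asks whether a list's genes move one way on balance and does not compare them with other genes. Beside the mean of a called list the text gives the range that holds 95% of the means of 10000 random lists of the same size, drawn to match the list's brightness in 40 bins.

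The fits were tested on simulated data with the spread of the siLin28a against siGFP comparison, over 23410 rows with 50 rows changed per size in each of 20 simulations. Rows changed by a log2 size of 0.5 were called in 0% of cases, those changed by 1 in 15.6%, by 2 in 78.4% and by 3 in 93.7%. A list shifted by 0.25 was called in 100% of 20 simulations over 19946 genes, in which genes varied independently.

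Alternatives were a replicate block, only the compared groups in the fit, a variance trend, a robust prior, 2 filters on dim rows, a further quantile normalization, a shift of each array to the same median, 1 row per gene, a fold threshold of 1.5, least squares without the shared prior, and leaving out each array in turn. The lists were run with the replicate block, among genes with a mean of at least 6, with the mean of a gene's rows, with the arrays shifted to the same median and without each array in turn. Cyclic loess normalization between arrays was added, for rows and lists, after a shift that depends on brightness had been seen. A planned comparison of genes with and without seed sites of the siRNAs and of let-7 was not run, because no transcript sequences were used here.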

Results

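The data set holds 6 arrays of A3-1 mouse ES cells, 2 untreated, 2 with the control siRNA against GFP and 2 with the siRNA against Lin28a, each siRNA for 48 h. The median over all 35556 rows was between 5.2 and 5.3 on the log2 scale in every array. The upper quartile was 7.2 in every untreated and siGFP array, and 7.0 and 7.1 in siLin28a replicate 1 and 2. Values of the 23410 tested rows correlated between any 2 arrays at a Pearson r between 0.991 and 0.995 across rows, which are not independent replicates. The r was 0.992 between the untreated arrays, 0.993 between the siGFP arrays and 0.994 between the siLin28a arrays. It was highest between groups, above every pair within a group, at 0.995 for siGFP and siLin28a replicate 1 and 0.995 for their replicate 2. It was 0.991 for untreated and siLin28a replicate 1. No 2 arrays held the same values, with at most 18.7% of tested rows equal between a pair.

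The targeted transcript was lower in both siLin28a arrays than in any other array. Lin28a encodes an RNA-binding protein that blocks the maturation of let-7 microRNAs. Its value was 9.1 and 9.4 in the untreated arrays, 9.1 and 9.4 in the siGFP arrays, and 7.4 in each siLin28a array. The log2 fold change was −1.85 (SE 0.16, n = 2 per group) against siGFP and against untreated cells, a 3.60-fold lower level. Lin28a had the smallest adjusted p of all rows in the comparison with siGFP, 0.512 by limma, which did not pass the threshold over 23410 rows. It passed when adjusted over the list of LIN28, terminal uridylation and small RNA machinery alone, at 4.38e-04. Its adjusted p was 0.0244 with a robust prior and 0.0232 with the arrays shifted to the same median. The related gene Lin28b had 6.1 and 6.6 in the siLin28a arrays and 6.1 and 6.5 in the siGFP arrays, a log2 fold change of 0.05 (SE 0.23), which was −0.15 without siGFP replicate 1 and −0.20 without siLin28a replicate 2. Moves of over 1.5 times came without siGFP replicate 2 (Lin28b 0.25) and siLin28a replicate 1 (Lin28b 0.30).

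The comparison of siLin28a with siGFP asks which transcripts differ when Lin28a is reduced and siRNA delivery is common to both groups. Transcripts of the naive and primed states, which resemble the embryo's cells before and after implantation, were among those with the smallest p. None of them passed the threshold over all rows, so they are given as values and not as calls. Tbx3, a transcription factor of naive ES cells, had a log2 fold change of −1.15 (SE 0.13, n = 2 per group, adjusted p 0.723 by limma). Dnmt3b, a de novo DNA methyltransferase of the post-implantation epiblast, had one of 1.15 (SE 0.13, adjusted p 0.723 by limma). Zic2, a transcription factor of primed cells, had a log2 fold change of 1.25 (SE 0.26), and Lef1, a transcription factor of the Wnt pathway, one of 0.95.

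The naive pluripotency list fell: 34 of its 36 genes were lower, 1 was higher and 1 was equal, and the mean log2 fold change was −0.32 (SD 0.29 over genes, median −0.25). Camera gave an adjusted p of 2.99e-11, and adjusted p = 0.452 with an estimated correlation. The 10000 random lists of the same brightness had means between −0.15 and −0.05. Of its members 0 passed over all rows and 7 passed when adjusted over the list alone. These 7 were Tbx3, Prdm14 (−0.80), Klf4 (−0.75), Nanog (−0.70), Zfp42 (−0.70), Jam2 (−0.65) and Tcl1 (−0.60). Nanog was at 10.9 and 11.3 in the siGFP arrays and at 10.3 and 10.5 in the siLin28a arrays. The core factors Pou5f1 and Sox2 had log2 fold changes of −0.20 (SE 0.14) and −0.20 (SE 0.15), and the exception in the list was Dnmt3l, a cofactor of DNA methylation, at 0.45. Values moved by over 1.5 times without siGFP replicate 2 (Pou5f1 −0.10, Sox2 −0.10) and siLin28a replicate 1 (Pou5f1 −0.10, Sox2 −0.10).

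The primed epiblast list rose: 15 of its 18 genes were higher, 1 was lower and 2 were equal, with a mean of 0.38 (SD 0.40 over genes, median 0.20). Camera gave an adjusted p of 1.76e-09, and adjusted p = 0.155 with an estimated correlation. Random lists of the same brightness had means between −0.14 and 0.03. Of its members 0 passed over all rows and 6 passed when adjusted over the list alone, namely Zic2, Dnmt3b, Lef1, Zic5 (0.70), Sox4 (0.60) and Pou3f1 (0.40). The means of both lists kept their direction and both calls held in all 6 fits that left out 1 array. Fits without an untreated array leave these means unchanged by construction.

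**Figure D1:**
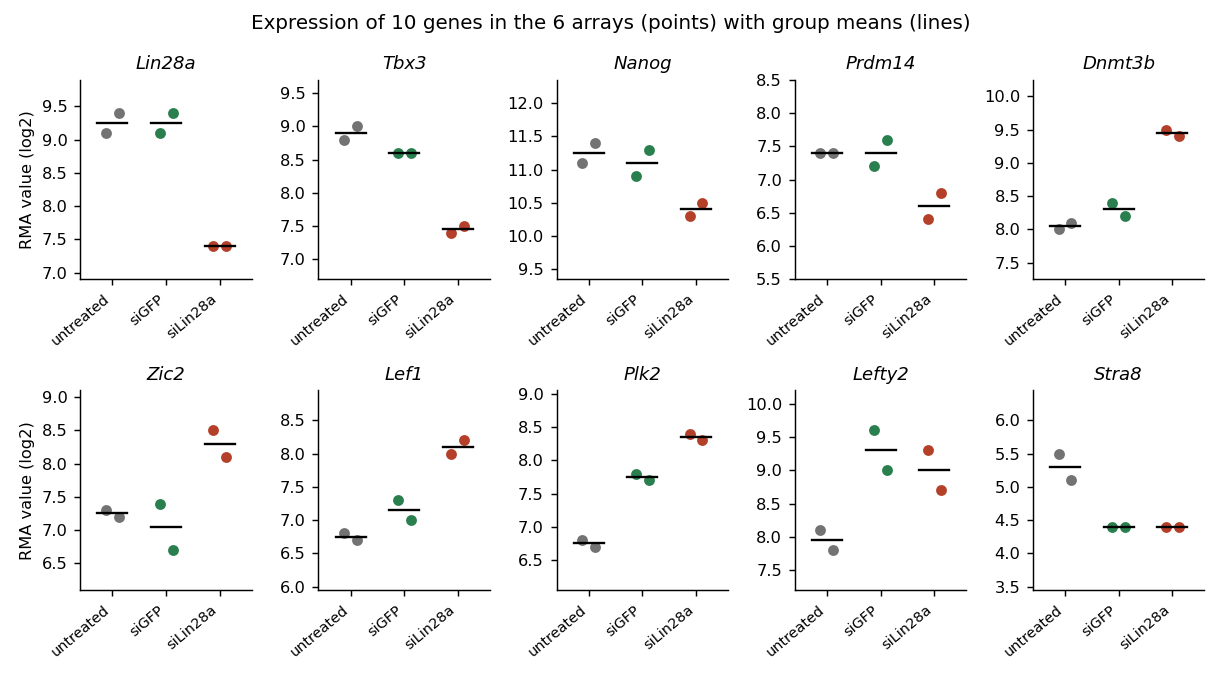
Log2 RMA value (vertical axis, a span of 3 log2 units in every panel) of 10 genes in the untreated, siGFP and siLin28a groups; points are the 2 arrays of a group and lines are group means. Lin28a is at 7.4 in both siLin28a arrays against 9.1 to 9.4 elsewhere, and Dnmt3b is at 9.4 and 9.5 there against 8.0 to 8.4 elsewhere.

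Lists of other cell types did not pass. The mean was 0.05 for mesoderm and definitive endoderm (adjusted p 0.216), 0.00 for primitive endoderm (0.641), 0.02 for neural ectoderm (0.578), −0.07 for trophoblast (0.875) and 0.05 for feeder fibroblasts (0.157). Members with the largest values included Sox11, a neural transcription factor, at 0.65 and the neuronal tubulin Tubb3 at −0.55, the trophoblast factors Tfap2c at −0.55 and Ets2 at −0.45, the endoderm-secreted Cer1 at 0.30 and Gsc at 0.25, the basement membrane and lipid transport genes Lama1 at −0.35 and Apoe at −0.40, and the stromal genes Timp3 at −0.40 and Acta2 at 0.35. The 25 measured let-7 target mRNAs had a mean of −0.08 and were not called (adjusted p 0.421), with 16 lower, 8 higher and 1 equal. Among them Nr6a1 had 0.45 (SE 0.19) and Myc −0.40 (SE 0.50), which was 0.15 without siGFP replicate 2 and 0.25 without siLin28a replicate 1. The LIN28, terminal uridylation and small RNA machinery list had a mean of −0.19 and an adjusted p of 0.0617. Its mean includes the siRNA target Lin28a itself at −1.85, and its median was −0.10. Tut4, a terminal uridylyltransferase that acts with LIN28A on let-7 precursors, had −0.40 (SE 0.22) in it. Values over 1.5 times apart came without siGFP replicate 1 (Myc −0.95, Tut4 −0.25, Cer1 0.05, Gsc 0.10, Lama1 −0.15), siGFP replicate 2 (Cer1 0.55, Gsc 0.40, Lama1 −0.55, Tubb3 −0.35, Timp3 −0.25), siLin28a replicate 1 (Cer1 0.15, Ets2 −0.25, Timp3 −0.25) and siLin28a replicate 2 (Myc −1.05, Lama1 −0.20, Sox11 0.40).

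Stress, histone and mitochondrial lists fell by smaller amounts. The integrated stress response list, targets of ATF4, had a mean of −0.21 (SD 0.21, 21 of 27 genes lower, random lists −0.13 to 0.00, adjusted p 0.00528), and adjusted p = 0.912 with an estimated correlation. Slc7a1, an amino acid transporter, and Chac1, which degrades glutathione, had −0.55 each (SE 0.26 and 0.47). They had −0.25 and 0.20 without siGFP replicate 1 and −0.85 and −1.30 without siGFP replicate 2, and Chac1 had −0.85 and −0.25 without siLin28a replicate 1 and 2. The call ended without siGFP replicate 1, which brought the mean to 0.00, and without siLin28a replicate 2, which brought it to −0.11. Without siGFP replicate 2 the mean was −0.42. Replication-dependent histones had a mean of −0.20 (SD 0.14, 26 of 27 lower, random lists −0.11 to 0.01, adjusted p 5.28e-04), and adjusted p = 0.912 with an estimated correlation. H2ac1 had −0.70 (−0.40 without siGFP replicate 1) and H3c15 −0.35 (−0.20 without siGFP replicate 2, −0.55 and −0.15 without siLin28a replicate 1 and 2). The histone call ended without siGFP replicate 2 (mean −0.14) and without siLin28a replicate 1 (mean −0.07), and the mean was −0.33 without siLin28a replicate 2. Oxidative phosphorylation had a mean of −0.11 (SD 0.11, 66 of 79 lower, adjusted p 5.28e-04), and adjusted p = 0.912 with an estimated correlation. Its mean lay within the range of random lists of the same brightness, −0.12 to −0.05, and its call ended without siGFP replicate 2 (mean −0.01) and after cyclic loess (mean −0.04). The mean was −0.21 without siGFP replicate 1 and −0.06 without siLin28a replicate 1. Ndufs6 and Atp5k, subunits of complex I and of the ATP synthase, had −0.35 each, and Atp5k had −0.55 and −0.15 without siGFP replicate 1 and 2. The list of ER chaperones and other targets of ATF6 and XBP1 had a mean of −0.13 (SD 0.12, 18 of 24 lower, adjusted p 0.0426), and adjusted p = 0.912 with an estimated correlation. This mean also lay within the range of its random lists, −0.16 to −0.02, with Herpud1 at −0.40 and Dnajb9 at −0.30. Herpud1 had 0.00 and −0.80 without siGFP replicate 1 and 2, and −0.20 without siLin28a replicate 2. The list's call ended without untreated replicate 1 (−0.13), siGFP replicate 1 (−0.16), siGFP replicate 2 (−0.10) or siLin28a replicate 1 (−0.05), after cyclic loess (−0.05), with the mean of a gene's rows (−0.12) and with genes of a mean under 6 left out (−0.13). Its mean was −0.20 without siLin28a replicate 2. The p53 target list rose, with a mean of 0.08 (SD 0.23, 15 of 22 higher, random lists −0.14 to 0.01, adjusted p 0.0426), and adjusted p = 0.68 with an estimated correlation. Its members Plk2, a kinase of the stress response, and Ddit4l, an inhibitor of mTOR signalling, had 0.60 and 0.55, and 1 member, Plk2, passed when adjusted over the list alone. That call ended without siGFP replicate 1 (0.06), siGFP replicate 2 (0.09), siLin28a replicate 1 (0.10) or siLin28a replicate 2 (0.05).

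The remaining lists were not called in this comparison. The means were −0.11 for ER translocation and N-glycosylation (adjusted p 0.0617), −0.08 for surface receptors and adhesion proteins (0.22), −0.08 for the cell cycle (0.24), −0.05 for ribosomal proteins (0.275), −0.08 for glycolysis (0.22), −0.09 for cholesterol biosynthesis (0.24) and −0.06 for the lysosome (0.421). They were 0.11 for germline genes (adjusted p 0.0644), 0.09 for the 2-cell-like state (0.22), 0.01 for the interferon response (0.641), −0.03 for immediate early genes (0.899) and −0.01 for housekeeping genes (0.964), and only the housekeeping list had a median, mean and test that differed in sign. The stem cell factor receptor Kit had −0.65 (SE 0.16), the tetraspanin Cd9 −0.40, Ifitm3, which restricts virus entry, 0.60 and Mx2 −0.50. The germline gene Mael had 0.65 and Rpl10l, listed with germline genes and with ribosomal proteins, 0.50. Other values were 0.45 for Rpl39l, −0.55 for Pramel6, 0.40 for Usp17lb, −0.50 for the checkpoint kinase Bub1, −0.40 for Ccne2, −0.35 for Pfkm, −0.30 for Pfkp, −0.45 for Elovl6, −0.35 for Ebp, 0.30 for Lipa, −0.30 for Hexa, 0.40 for Egr1, 0.35 for Zfp36, −0.30 for Spcs1, −0.30 for Sec62 (0.15 without siLin28a replicate 1), 0.20 for Gusb and −0.15 for Sdha. Other moves of over 1.5 times came without siGFP replicate 1 (Rpl10l 0.30, Sec62 −0.55, Elovl6 −0.25, Ebp −0.60), siGFP replicate 2 (Pramel6 −0.35, Spcs1 −0.15, Sec62 −0.05, Ccne2 −0.25, Ebp −0.10, Lipa 0.15, Egr1 0.20), siLin28a replicate 1 (Pramel6 −0.30, Spcs1 −0.15, Mx2 −0.80, Ccne2 −0.25, Hexa −0.50) and siLin28a replicate 2 (Sec62 −0.75, Mx2 −0.20, Lipa 0.15, Hexa −0.10).

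Over all rows, 0 of 23410 passed by limma in the comparison of siLin28a with siGFP, and 949 had an unadjusted p under 0.05 (419 higher and 530 lower) where chance gives 1170. Least squares without the shared prior called 0 and gave 943. The 5 highest-ranked higher rows were Dnmt3b, Car4 (1.10), Bcl11a (1.05), Pim2 (1.25) and Vrtn (1.05), and the 5 lower ones were Lin28a, Tbx3, Rnf213 (−0.80), Dnajc6 (−0.75) and Slc13a5 (−0.90). Rows with a change of at least 2-fold numbered 13 higher and 7 lower. Of the 62 values of named genes 29 moved by over 1.5 times or turned without at least 1 array. These 62 leave out members named only because they passed when adjusted over their list alone. The share of higher rows among those with an unadjusted p under 0.05 was 44.2%, and it was 32.0% with the arrays shifted to the same median. It was 48.3% with a further quantile normalization and 48.6% after cyclic loess. Rows with a mean between 8 and 10 had a mean log2 fold change of −0.10 and rows with a mean between 4 and 6 one of 0.02. The former was −0.0034 with a further quantile normalization and −0.0052 after cyclic loess.

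**Figure D2:**
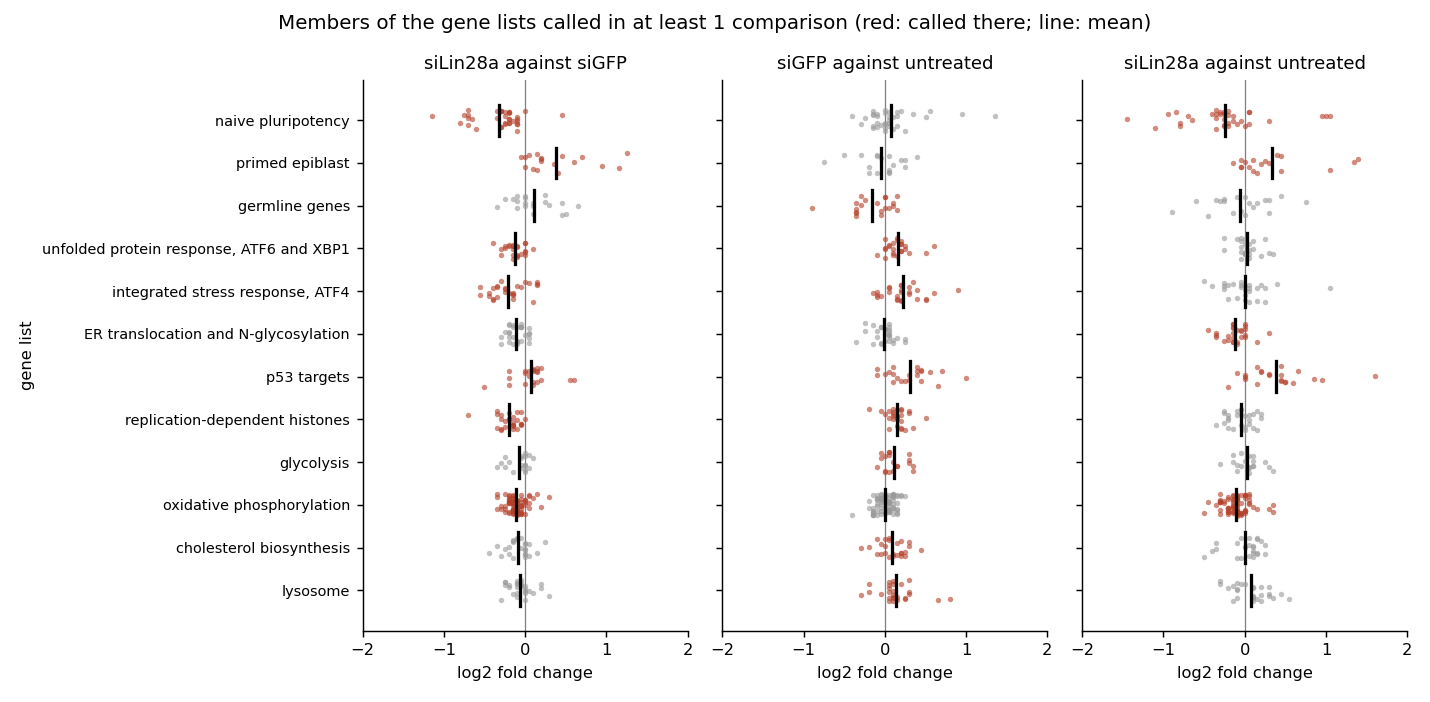
Log2 fold change (horizontal axis) of each member (points) of the gene lists called in at least 1 comparison, with the list's mean (black line), for the 3 comparisons; red points mark lists called there and grey points lists not called. In siLin28a against siGFP the naive pluripotency mean is −0.32 and the primed epiblast mean 0.38, and in siGFP against untreated the p53 target mean is 0.31.

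The comparison of siGFP with untreated cells shows what accompanied the control siRNA itself. The p53 target list rose, with 19 of its 22 genes higher, 2 lower and 1 equal, a mean log2 fold change of 0.31 (SD 0.27 over genes, median 0.30) and random lists between −0.06 and 0.09. Cdkn1a, Bax and Gdf15 were listed as p53 targets but had no row of their own, so they are not among the 22. Camera gave an adjusted p of 1.20e-09, and adjusted p = 0.155 with an estimated correlation. Plk2 was at 6.8 and 6.7 in untreated cells and at 7.8 and 7.7 with siGFP, a log2 fold change of 1.00 (SE 0.12, n = 2 per group). Of the members 0 passed over all rows and 5 when adjusted over the list alone: Plk2, the inhibitor of Akt signalling Phlda3 (0.70), the adhesion gene Perp (0.65), Ccng1 (0.55) and Btg2 (0.45). The call held in all 6 fits that left out 1 array, with means between 0.29 and 0.33. Fits without a siLin28a array leave this mean unchanged by construction.

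Between siGFP and untreated cells, Lefty2 and Lefty1, secreted inhibitors of Nodal signalling that were listed under naive pluripotency, had log2 fold changes of 1.35 (SE 0.28) and 0.95 (SE 0.20), and these 2 passed when adjusted over the list alone. The naive list as a whole was not called, with a mean of 0.08 (adjusted p 0.493), and Pou5f1, Sox2 and Nanog had −0.05, −0.10 and −0.15 (SE 0.14, 0.15 and 0.19). The primed epiblast list had a mean of −0.05 (adjusted p 0.639), with Zic5 at −0.75 and Dnmt3a at −0.50. Lin28a had 0.00 and Lin28b −0.15. Without siGFP replicate 1, Pou5f1, Nanog and Lin28b each had 0.05. Shifts of over 1.5 times were seen without untreated replicate 1 (Pou5f1 −0.10, Sox2 0.00, Nanog −0.30, Lin28b 0.00), untreated replicate 2 (Pou5f1 0.00, Sox2 −0.20, Nanog 0.00, Lin28b −0.30), siGFP replicate 1 (Sox2 0.00) and siGFP replicate 2 (Pou5f1 −0.15, Sox2 −0.20, Nanog −0.35, Lin28b −0.35).

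Several stress and metabolic lists rose in siGFP against untreated cells. The ATF4 list had a mean of 0.22 (SD 0.24, 22 of 27 higher, random lists −0.06 to 0.08, adjusted p 7.69e-04), and adjusted p = 0.912 with an estimated correlation. Ddit4, an inhibitor of mTOR signalling, had 0.90 (SE 0.19). Chac1 had 0.60 (SE 0.47), from 8.2 in siGFP replicate 1 and 6.7 in replicate 2, and had −0.15 and 1.35 without siGFP replicate 1 and 2. The call ended without siGFP replicate 1 (mean 0.00) and without untreated replicate 1 (mean 0.07). The mean was 0.43 without siGFP replicate 2 and 0.36 without untreated replicate 2. The ATF6 and XBP1 list had a mean of 0.16 (SD 0.16, 19 of 24 higher, adjusted p 0.00365), histones one of 0.15 (SD 0.13, 24 of 27 higher, adjusted p 0.00365), the lysosome one of 0.13 (SD 0.23, 23 of 27 higher, adjusted p 0.00253), glycolysis one of 0.11 (SD 0.14, 13 of 19 higher, adjusted p 0.0202) and cholesterol biosynthesis one of 0.09 (SD 0.17, 16 of 25 higher, adjusted p 0.0487). For each of these 5 lists adjusted p = 0.912 with an estimated correlation. Random lists had means between −0.06 and 0.08 for the ATF6 and XBP1 list, −0.06 and 0.08 for histones, −0.06 and 0.07 for the lysosome, −0.07 and 0.07 for glycolysis, and −0.06 and 0.07 for cholesterol biosynthesis. Examples were the chaperones Hsp90b1 (0.60) and Hspa5 (0.50), H2ac1 (0.50), H4c3 (0.35), Cd63 (0.80), Hexa (0.65), Pfkfb3 (0.35), Aldoc (0.35), Scd1 (0.45) and Srebf1 (0.30), of which Cd63 alone passed when adjusted over its list alone. Hsp90b1 stood at 9.6 in untreated replicate 2 and between 10.5 and 10.9 in the other 5 arrays. Without untreated replicate 1 and 2, Hsp90b1 had 1.25 and −0.05, Hspa5 0.95 and 0.05, H4c3 0.15 and 0.55, and H2ac1 0.20 and 0.80, and H2ac1 also had 0.20 and 0.80 without siGFP replicate 1 and 2. Without siGFP replicate 2 the calls ended for the ATF6 and XBP1 list (mean 0.12), histones (0.09), glycolysis (0.08) and cholesterol biosynthesis (0.03). Without untreated replicate 1 they ended for histones (0.05), the lysosome (0.05), glycolysis (0.04) and cholesterol biosynthesis (0.06), without untreated replicate 2 for the ATF6 and XBP1 list (0.12) and cholesterol biosynthesis (0.11), and without siGFP replicate 1 for the lysosome (0.12). The cholesterol call also ended after cyclic loess (0.09), with the arrays shifted to the same median (0.06), with the mean of a gene's rows (0.09) and with genes of a mean under 6 left out (0.09).

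The germline list fell, with a mean of −0.16 (SD 0.26, 12 of 20 lower, random lists −0.07 to 0.09, adjusted p 0.00421), and adjusted p = 0.453 with an estimated correlation. Stra8, a gene that marks entry into meiosis, was at 5.5 and 5.1 in untreated cells and at 4.4 in both siGFP arrays, a log2 fold change of −0.90 (SE 0.16), and was the 1 member that passed when adjusted over the list alone. Piwil2, of the piRNA pathway, had −0.35 (−0.20 without untreated replicate 2). The call ended without untreated replicate 1 (−0.11), without siGFP replicate 2 (−0.09) and with genes of a mean under 6 left out (−0.11). The interferon response, which double-stranded RNA can induce, had a mean of 0.02 (adjusted p 0.875), with Oas2 and Tlr3 at −0.45 each. The let-7 target list had a mean of −0.02 (adjusted p 0.802), with Ccnd2, the cyclin D2 gene, at −1.05 (SE 0.52) and Hmga2 at 0.35. Ccnd2 was at 9.7 and 9.4 in untreated cells, and at 7.8 and 9.2 with siGFP, and had −0.35 and −1.75 without siGFP replicate 1 and 2. Values over 1.5 times apart were found without untreated replicate 1 (Tlr3 −0.25), siGFP replicate 1 (Tlr3 −0.20) and siGFP replicate 2 (Tlr3 −0.70).

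Means of the lists not called in siGFP against untreated cells lay between −0.05 for the primed epiblast list and 0.08 for the naive list. The median, mean and test differed in sign for 6 of these, the let-7, LIN28, neural, trophoblast, 2-cell-like and housekeeping lists. Their members included Tut4 (0.45), Tut7 (0.30), Eomes (0.45), Cer1 (−0.35), Apoe (0.50), Sparc (−0.35), Pax6 (−0.45), Map2 (0.40), Rhox9 (0.35), Tpbpa (−0.25), Thy1 (−0.40), Tagln (0.25), Tmem92 (0.40), Pramel6 (0.40), Srp14 (−0.35), Dad1 (−0.25), Cd24a (0.90), Itgav (0.50), the proliferation marker Mki67 (0.90), Rpl39l (−0.30), Rps3 (0.25), Atp5l (−0.40), Cox7a2l (0.25), Dusp4 (0.60), Egr1 (−0.50), Polr2a (0.50) and B2m (0.40). Changes of over 1.5 times in value came without untreated replicate 1 (Tut4 0.75, Eomes 0.70, Cer1 −0.55, Sparc −0.60, Tpbpa −0.45, Pramel6 0.70, Dad1 −0.40, Cox7a2l 0.15), untreated replicate 2 (Tut4 0.15, Tut7 0.15, Eomes 0.20, Cer1 −0.15, Sparc −0.10, Tpbpa −0.05, Pramel6 0.10, Dad1 −0.10, Atp5l −0.25, Egr1 −0.30), siGFP replicate 1 (Tut7 0.15, Eomes 0.25, Cer1 −0.10, Sparc −0.15, Rhox9 0.70, Srp14 −0.20, Dad1 −0.05, Atp5l −0.25, Cox7a2l 0.40, Dusp4 0.30, B2m 0.20) and siGFP replicate 2 (Cer1 −0.60, Sparc −0.55, Rhox9 0.00, Pramel6 0.20, Dad1 −0.45, Cox7a2l 0.10, Egr1 −0.30).

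In siGFP against untreated cells, 0 of 23410 rows passed by limma, and 825 had an unadjusted p under 0.05 (513 higher and 312 lower) where chance gives 1170, while least squares without the shared prior called 0 and gave 835. The lowest adjusted p was 0.961. The highest-ranked higher rows were Plk2, Serpinb6c (1.05), Penk (0.80), Laptm5 (0.95) and Pomgnt1 (0.65), and the lower ones were Gnat2 (−0.60), Actn3 (−0.70), Syt11 (−0.70), Zic5 and Gdpd1 (−0.50). Rows with a change of at least 2-fold numbered 12 higher and 4 lower. Without at least 1 array, 27 of the 64 values of named genes moved by over 1.5 times or turned. The share of higher rows among those with an unadjusted p under 0.05 was 62.2%, and it was 46.7% with the arrays shifted to the same median. It was 57.9% with a further quantile normalization and 55.9% after cyclic loess.

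**Figure D3:**
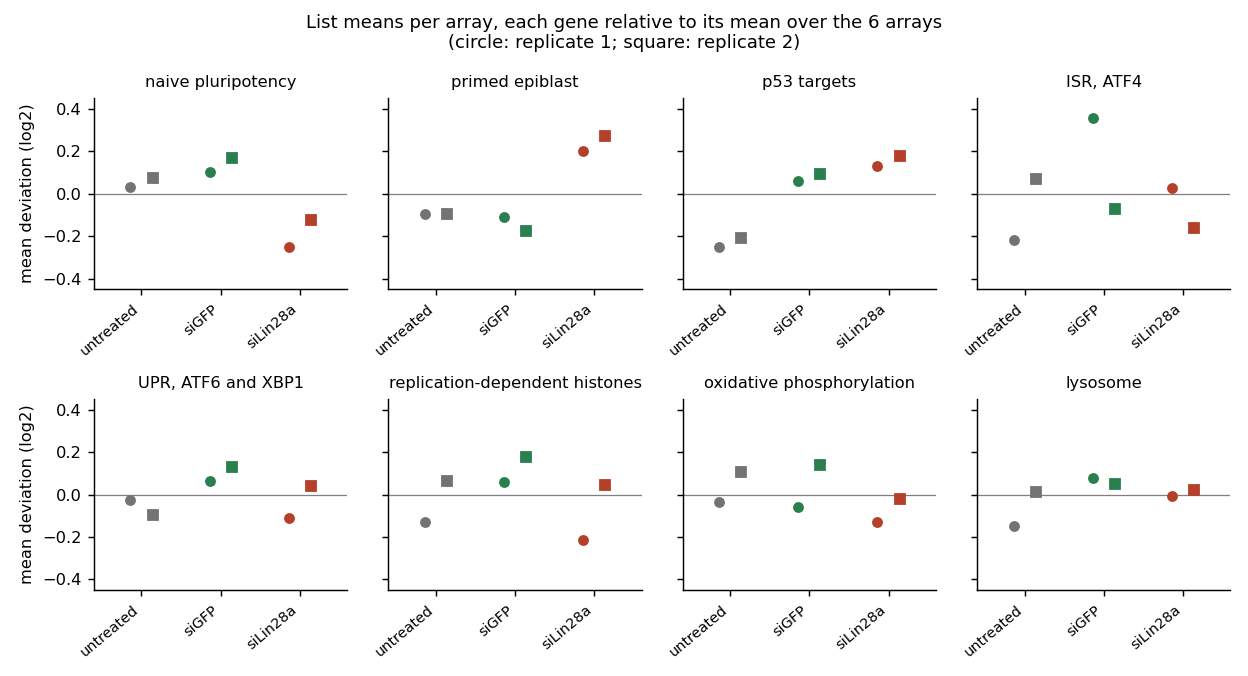
Mean over the genes of 8 lists (vertical axis, log2 deviation of each gene from its mean over the 6 arrays) in each array of the 3 groups; circles are replicate 1 and squares replicate 2. The naive list is at −0.25 and −0.13 in the siLin28a arrays and between 0.03 and 0.17 in the other arrays, and the ATF4 list is at 0.36 in siGFP replicate 1 and at −0.07 in siGFP replicate 2.

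The comparison of siLin28a with untreated cells combines the reduction of Lin28a with siRNA delivery. Plk2 stood at 8.4 and 8.3 with siLin28a against 6.8 and 6.7 in untreated cells, a log2 fold change of 1.60 (SE 0.12, n = 2 per group). Tbx3 had −1.45 (SE 0.13), Dnmt3b 1.40 (SE 0.13) and Lef1 1.35 (SE 0.15). Nanog had −0.85 (SE 0.19), Pou5f1 −0.25 (SE 0.14), Sox2 −0.30 (SE 0.15) and Lin28b −0.10 (SE 0.23), which was 0.05 without untreated replicate 1 and 0.15 without siLin28a replicate 1. The naive list fell with a mean of −0.24 (SD 0.52 over genes, 28 of 36 lower, random lists −0.17 to −0.03, adjusted p 5.53e-06), and adjusted p = 0.68 with an estimated correlation. The primed list rose with a mean of 0.33 (SD 0.47, 13 of 18 higher, random lists −0.15 to 0.07, adjusted p 6.72e-05), and adjusted p = 0.312 with an estimated correlation. The p53 target list rose with a mean of 0.38 (SD 0.40, 17 of 22 higher, random lists −0.15 to 0.04, adjusted p 1.33e-10), and adjusted p = 0.155 with an estimated correlation. These 3 calls held in all 6 fits that left out 1 array. Fits without a siGFP array leave the means of these lists unchanged by construction. Moves of over 1.5 times came without untreated replicate 2 (Lin28b −0.25), siLin28a replicate 1 (Pou5f1 −0.15) and siLin28a replicate 2 (Lin28b −0.35).

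Of the naive list's members 0 passed over all rows and 11 when adjusted over the list alone. Of those, 8 were lower, namely Tbx3, the DNA demethylase gene Tet2 (−1.10), Tfcp2l1 (−0.95), Nanog, Prdm14 (−0.80), Jam2 (−0.80), Zfp42 (−0.70) and Klf4 (−0.65), and 3 were higher, Lefty2 (1.05), Dnmt3l (1.00) and Lefty1 (0.95). The 4 primed members that passed when adjusted over the list alone were Dnmt3b, Lef1, Zic2 (1.05) and Pou3f1 (0.45). For p53 targets 6 passed when adjusted over the list alone, namely Plk2, Ddit4l (0.95), Phlda3 (0.85), Perp (0.65), Ccng1 (0.60) and Btg2 (0.45). Ddit4 (1.05) passed when adjusted over the ATF4 list alone, and Stra8 (−0.90) and Dazl (−0.60), genes of germ cells, over the germline list alone. Lin28a passed when adjusted over its list alone, at 4.38e-04.

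Oxidative phosphorylation fell with a mean of −0.11 (SD 0.15, 61 of 79 lower, adjusted p 0.00149), and adjusted p = 0.912 with an estimated correlation. ER translocation and N-glycosylation, the machinery that inserts and glycosylates membrane and secreted proteins, fell with a mean of −0.12 (SD 0.15, 21 of 28 lower, adjusted p 0.0449), and adjusted p = 0.912 with an estimated correlation. Both means lay within the ranges of random lists of the same brightness, −0.13 to −0.04 and −0.17 to −0.02. Cox7a1 (−0.50), Atp5l (−0.45), Srp19 (−0.45) and Srp14 (−0.35) had the largest values. Without siLin28a replicate 1, Cox7a1 had −0.30, Srp19 −0.20 and Srp14 −0.20, and Srp19 had −0.25 without untreated replicate 1 and −0.70 without siLin28a replicate 2. The first call ended without untreated replicate 2 (−0.04), after cyclic loess (−0.03) and with genes of a mean under 6 left out (−0.12). Its mean was −0.18 without untreated replicate 1 and −0.06 without siLin28a replicate 1. The second call ended without untreated replicate 1 (−0.13), untreated replicate 2 (−0.11) or siLin28a replicate 1 (0.00), after cyclic loess (−0.04) and with genes of a mean under 6 left out (−0.12). Its mean was −0.24 without siLin28a replicate 2.

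Means of the lists not called in siLin28a against untreated cells lay between −0.19 for the LIN28 list and 0.10 for the 2-cell-like state. The LIN28 list includes the siRNA target Lin28a itself, and its median was −0.10. The let-7 target list had a mean of −0.11 (adjusted p 0.727), with Ccnd2 at −1.20 (SE 0.52) and Dusp9 at −0.70, which were −0.65 and −0.45 without siLin28a replicate 1. The ATF4 list had 0.01 (adjusted p 0.875), the ATF6 and XBP1 list 0.03 (adjusted p 0.69) and histones −0.05 (adjusted p 0.641), and 4 lists (neural, trophoblast, surface receptor and ribosomal) had a median, mean and test that differed in sign. Named members included Tnrc6c (−0.55), Eomes (0.45), Tbx6 (0.15), Sparc (−0.50), Pth1r (0.25), Tubb3 (−0.85), Sox11 (0.65), Tfap2c (−0.55), Ets2 (−0.40), Timp3 (−0.45), Thy1 (−0.30), Usp17lc (0.40), Tmem92 (0.30), Mael (0.75), Hsp90b1 (0.35) and Hspa5 (0.30), at −0.30 and −0.15 without untreated replicate 2, the amino acid transporter Slc7a1 (−0.50), Kit (−0.80), the alkaline phosphatase Alpl (−0.65), Ifitm3 (0.55), Ifitm1 (−0.50), Mki67 (0.95), H1f2 (−0.35), H2bc8 (−0.25), Rpl10l (0.45), Rpl7l1 (−0.30), Pfkfb3 (0.35), Pfkp (−0.30), Elovl6 (−0.50), Ebp (−0.40), Cd63 (0.55), Lipa (0.45), Dusp4 (0.60), Spry4 (−0.45), Polr2a (0.55) and B2m (0.35). Values moved by over 1.5 times without untreated replicate 1 (Eomes 0.70, Hsp90b1 1.00, Hspa5 0.75, Ifitm3 0.25, H1f2 −0.20), untreated replicate 2 (Eomes 0.20, Sparc −0.25, Pth1r 0.15, Slc7a1 −0.25, Ifitm3 0.85, Pfkp −0.15, Spry4 −0.25), siLin28a replicate 1 (Tbx6 0.25, Sparc −0.25, Ets2 −0.20, Usp17lc 0.70, Alpl −0.40, H1f2 −0.15, H2bc8 −0.05, Dusp4 0.30, Spry4 −0.20) and siLin28a replicate 2 (Tbx6 0.05, Sox11 0.40, Usp17lc 0.10, Hspa5 0.15, H1f2 −0.55, H2bc8 −0.45, Spry4 −0.70).

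In siLin28a against untreated cells, 0 of 23410 rows passed by limma and 1508 had an unadjusted p under 0.05 (676 higher and 832 lower) where chance gives 1170, while least squares without the shared prior called 0 and gave 1221. The lowest adjusted p was 0.171, shared by Lin28a, Tbx3 and Plk2. With a robust prior 7 rows passed, among them Lin28a, Tbx3, Plk2, Dnmt3b, Lef1 and Vrtn, and 3 passed with the arrays shifted to the same median and 3 after cyclic loess, in both cases Plk2, Lin28a and Tbx3. The other highest-ranked rows were Vrtn (1.40) and Tek (1.10), which were higher, and Rnf213 (−0.95 and −0.90 in 2 rows) and Kbtbd8 (−1.0), which were lower. Rows with a change of at least 2-fold numbered 30 higher and 27 lower. Among 60 values of named genes, 24 moved by over 1.5 times or turned without at least 1 array. The share of higher rows among those with an unadjusted p under 0.05 was 44.8%, and it was 25.3% with the arrays shifted to the same median. It was 50.4% with a further quantile normalization and 48.7% after cyclic loess.

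Against both controls at once, 0 rows passed. At an unadjusted p under 0.05 in both, 138 rows were higher and 250 lower with siLin28a. Simulated unchanged groups that share the siLin28a arrays gave 179 and 174 such rows, and independent lists of these sizes would share 12.1 and 18.8. The log2 fold changes of the 2 comparisons correlated at r = 0.605 across rows against 0.498 in simulation, with a covariance of 0.0258 against 0.0306 in simulation. Both siRNA groups against untreated cells had 203 rows higher and 123 lower in both, against 180 and 175 in simulation and 14.8 and 11.1 for independent lists. Their correlation was 0.572 against 0.507 in simulation and the covariance 0.0237 against 0.0314. With 2 arrays per group the controls could be split only into single arrays. The siGFP and siLin28a differences from separate untreated arrays then correlated at r between −0.135 and 0.296, and part of any excess may come from the shared arrays.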

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

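The naive, primed and p53 calls that held without each array in turn also held with the arrays shifted to the same median, after cyclic loess, among genes with a mean of at least 6 and with the mean of a gene's rows, and 0 of the called lists was called with an estimated correlation or by fry. Called lists numbered 7 for siLin28a against siGFP, 8 for siGFP against untreated and 5 for siLin28a against untreated by camera, against 0, 0 and 0 with an estimated correlation between genes and 0, 0 and 0 with fry. Without 1 array they numbered 5 to 10, 2 (without untreated replicate 1) to 8 (without siGFP replicate 1; 5 without siGFP replicate 2) and 4 to 6. Over all genes named by the rule and all settings 3055 values kept their side of the threshold without turning, 12 became stronger and 15 reversed. This count says little about stability, since many settings leave a log2 fold change unchanged by construction. A value that fell to 0 counts as kept, as Herpud1 did in siLin28a against siGFP without siGFP replicate 1. For called lists 174 stayed the same, 84 became weaker and 2 reversed by the direction of camera, which compares a list with other genes. The ER translocation mean in siLin28a against untreated turned from −0.12 to 0.00 (0.0036) without siLin28a replicate 1 while camera's direction stayed. Rows called by limma numbered 0 in every comparison and every fit without 1 array. They numbered 1 (Lin28a) for siLin28a against siGFP with a robust prior and 1 with the arrays shifted to the same median, where Lin28a had −1.85 and −1.88. For siLin28a against untreated they numbered 7 with a robust prior, 3 with the arrays shifted to the same median and 3 after cyclic loess, and against both controls 1 with a robust prior and 1 with the shifted arrays; the cause was not tested. Lin28a ranged from −2.0 to −1.7 without 1 array.

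Fits without 1 array leave a group with a lone sample, assumed to vary as the other groups do, and the cause of the reversals below was not tested. For siLin28a against siGFP the ranges over these 6 fits were −0.20 to 0.30 for Lin28b, −1.05 to 0.25 for Myc, −1.30 to 0.20 for Chac1, −0.75 to 0.15 for Sec62 and −0.42 to 0.00 (0.0037) for the ATF4 list. For siGFP against untreated they were −0.15 to 0.05 for Pou5f1, −0.35 to 0.05 for Nanog, −0.35 to 0.05 for Lin28b, −0.05 to 1.25 for Hsp90b1, −0.15 to 1.35 for Chac1 and 0.00 (0.0037) to 0.43 for the ATF4 list. For siLin28a against untreated they were −0.35 to 0.15 for Lin28b, −0.30 to 1.00 for Hsp90b1 and −0.15 to 0.75 for Hspa5. Rows with an unadjusted p under 0.05 numbered 949, 825 and 1508, against 185, 134 and 421 with at least a 1.5-fold change asked for, 443, 365 and 921 among rows with a mean of at least 6, and 489, 424 and 1003 above the median row mean, where fewer rows pass by construction. They numbered 1463 for siLin28a against siGFP with only these groups in the fit or without either untreated array, and 1626 and 1368 for siGFP against untreated without untreated replicate 1 and 2. With the replicate number as a block they numbered 1350, 1255 and 1933, each above the 1170 that chance gives, while 949 and 825 lie below it. With this block 0 rows were called, and the ATF4 call by camera in siLin28a against siGFP ended (adjusted p 0.0517). Deviations from the group mean correlated between arrays of the same number at r = 0.357, 0.154 and −0.0352. Of 6 arrays 5 lay closest, outside their group, to an array of their own number. In the same order of comparisons, differences from unshared arrays correlated across rows at r = 0.217, −0.026 and 0.088 within numbers. With crossed numbers they correlated at −0.152, −0.181 and 0.121.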

Other observations

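The cyclic loess fits, the tests of other cell types, of the siRNA sequence and of handling, the tests of the ATF4, ER chaperone and histone lists by parts, and the use of random lists as a test were chosen after the results were seen; the other tests below were written down before.

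Rows that gene copies share, chosen after their values were seen, stood apart in the siLin28a arrays. Zscan4 genes are expressed in bursts in a small share of ES cells that resemble the 2-cell embryo. The 3 rows that each match 5 Zscan4 copies (Zscan4a, Zscan4b, Zscan4c, Zscan4d and Zscan4f, not told apart) had log2 fold changes of 1.85 (SE 0.27), 1.90 (SE 0.27) and 1.90 (SE 0.37) against siGFP, with an adjusted p of 0.951 for the first. The first row was at 4.7 and 4.4 in untreated cells, 4.6 and 4.5 with siGFP, and 6.0 and 6.8 with siLin28a. A row shared by 9 predicted genes, among them Gm4340, Gm8764 and Gm6763, had 2.05 (SE 0.26), and a row shared by 13 had 0.80 (SE 0.22). The fixed 2-cell-like list, with 8 genes measured by rows of their own, was not called (mean 0.09, adjusted p 0.22).

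The naive list fell and the primed list rose in siLin28a against siGFP (adjusted p = 0.452 and adjusted p = 0.155 with an estimated correlation). A shift that depends on brightness does not account for it as the whole cause, since the naive mean was −0.24 after cyclic loess and the call held, and nor does a single array, since both calls held in 4 of 4 fits without 1 siGFP or siLin28a array. A lower share of ES cells with more cells of other types cannot be told apart: the 93 members of the 5 other cell type lists had a mean of 0.0151 (SD 0.21) and went both ways, but those bright in ES cells would hide a small share and the dim ones lie near the floor. An effect of this siRNA sequence other than through Lin28a cannot be told apart, because the design has 1 siRNA sequence against Lin28a. Hypothesis: reduced Lin28a may move these cells from naive towards primed expression, which a further siRNA sequence or a rescue would test.

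The ATF4, ER chaperone and histone lists rose in siGFP against untreated cells and fell in siLin28a against siGFP (adjusted p = 0.912 for each with an estimated correlation). Both comparisons use the same siGFP arrays with opposite sign, so spread in siGFP alone can give such a pair. In siLin28a against untreated, which uses no siGFP array, the means were 0.01, 0.03 and −0.05 without a call by camera. The ATF4 and histone means lay within the ranges of their random lists there, −0.14 to 0.03 and −0.12 to 0.04. The ER chaperone mean lay above its range, −0.17 to 0.00625, so spread in siGFP alone need not account for that list. For the ATF4 list a single siGFP array is a candidate explanation, since its mean in siGFP against untreated went from 0.22 to 0.00 (0.0037) without siGFP replicate 1. For the other lists it cannot be told apart: the ER chaperone call in siLin28a against siGFP ended without either siGFP array and the other calls without siGFP replicate 2, but at least 0.617 of each mean remained without either siGFP array, and a fit with fewer arrays also loses calls, so the rule written before, by which any lost call would count, was not used. A shift that depends on brightness does not account for the ATF4 and histone lists as the whole cause, whose means in siLin28a against siGFP were −0.15 and −0.16 after cyclic loess with the calls kept, nor for siGFP against untreated, where the ATF4, ER chaperone and histone means of 0.22, 0.16 and 0.15 lie above the upper ends of random lists of the same brightness, 0.0778, 0.0750 and 0.0759. For the ER chaperone list in siLin28a against siGFP it may, since the mean went from −0.13 (SD 0.12 over genes) to −0.0500 (SD 0.11) and the call ended because the mean shrank (adjusted p 0.589).

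The p53 target list rose in siGFP against untreated cells (adjusted p = 0.155 with an estimated correlation). A shift that depends on brightness does not account for it, since its mean of 0.31 lies above the upper end of random lists of the same brightness, 0.0932, and nor does a single array, since the call held in 4 of 4 fits without 1 untreated or siGFP array. Handling other than the siRNA, such as the transfection itself, cannot be told apart, because 0 arrays were mock-treated.

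Rows annotated to let-7 microRNA genes do not measure mature let-7, and their values lay between 2.1 and 5.9. Their log2 fold changes lay between −0.25 (Mirlet7d, Mirlet7a-2, Mirlet7g and Mirlet7f-2) and 0.10 (Mirlet7c-1) in siLin28a against siGFP. They lay between −0.35 (Mirlet7f-1) and 0.35 (Mirlet7a-2) in siGFP against untreated. In siLin28a against untreated they lay between −0.55 (Mirlet7f-1, adjusted p 0.776 by limma) and 0.25 (Mirlet7c-1). Of the 12146 rows without a gene 0 were called, and 457, 534 and 622 had an unadjusted p under 0.05 in siLin28a against siGFP, siGFP against untreated and siLin28a against untreated, where chance gives 607. One such row was at 1.4 and 1.7 in untreated cells, 4.0 and 4.6 with siGFP, and 1.3 and 1.4 with siLin28a, and another at 1.0 and 1.0, 3.4 and 4.0, and 1.0 and 1.2. Both were picked for the smallest p among these rows. Their adjusted p by limma was 0.517 in siLin28a against siGFP and 0.480 in siGFP against untreated. Their low values lie near the 1st percentile of the arrays, which was between 1.0 and 1.5.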
